A study of Mus musculus with 6 samples.

How the data were processed

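Single-nucleus RNA sequencing was done on microdissected hippocampi with 10x Genomics 3' chemistry, per the labels' protocols. Each of the 6 libraries had its own combination of injury (sham or TBI), vector (AAV-GFP or AAV-VEGFC) and side (right or left). Cell Ranger 7.0.1, Scanpy and the mm10 build are named in the submitters' processing notes, and their settings are not given in the sources used here.

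The deposited matrix holds raw UMI counts per gene and nucleus, and all its values are whole. The deposited metadata give for each nucleus its library, the authors' cell class and cluster, its total count, the percent of UMIs from mitochondrial and ribosomal protein genes, and a doublet score whose tool is not given in the sources used here. All deposited nuclei had over 1000 UMIs, under 1% mitochondrial UMIs and a doublet score of at most 0.099, so nuclei above these limits were not seen. No doublet caller was run, since the deposited scores end at this limit, and all deposited nuclei were kept. Totals were 15358208 to 18379148 UMIs per library. Class sums ranged from 45757 UMIs in the smallest fibroblast library to 10758968 in the largest excitatory neuron library, so folds in fibroblasts and microglia are the least precise.

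Counts were summed over the nuclei of each class in each library, for the 9 classes of the authors, all of which had at least 20 nuclei in every library. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM normalization, in 1 additive model with a term for context (sham right, TBI right, TBI left) and a term for vector. This leaves 2 residual degrees of freedom. The 3 tested comparisons were VEGFC against GFP over the 3 contexts, TBI right against sham right, and TBI left against TBI right. P-values were adjusted by the Benjamini-Hochberg method within class and comparison, with a threshold of 0.05. Each SE is the absolute log2 fold divided by the square root of the F statistic of the edgeR test. It holds spread borrowed from other genes, so it does not directly measure how far the libraries disagree. The last 2 comparisons share the TBI right libraries. Whether VEGFC acted differently after TBI than after sham has 1 library per combination in the right hippocampus, so differences of folds are given with counting intervals, and a further edgeR test, planned beforehand, took the left and right TBI libraries as replicates.

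Shares of nuclei have exact Clopper-Pearson 95% intervals, and levels of single genes have exact Poisson intervals, both of which cover counting error only. Vector ratios of shares were tested by an exact two-sided sign-flip permutation over the 3 contexts, for which the smallest possible p is 0.25. For gene lists, 37 in number, camera of limma 3.58.1 was run with a preset correlation between genes of 0.01 on lists with at least 5 tested members, and again with an estimated correlation. The lists covered microglial, astrocyte and oligodendrocyte states, immune and stress responses, synapses, metabolism, vessels and markers of neighbouring tissue.

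The comparisons, the lists, the first set of alternative settings and the rule for named genes were fixed before the data were examined. By this rule, Vegfc, Mapt, Flt4, Kdr and Flt1 are given in every case. For each comparison it takes up to 12 genes in each direction with the largest change among those past the threshold with a mean of at least 10 CPM and the same direction in every matched pair of libraries. Where fewer than 5 pass in a direction, the 5 with the smallest p are added as not past the threshold. For a list past the threshold it takes up to 4 members with the smallest p, and for the untested differences of folds the 5 largest and the 5 smallest with at least 50 counts in each library. Gene models with clone names were counted and not named. The rule was applied to the classes and again to the neuron subsets, which were formed after seeing the data. Coordinates are those of the mm10 annotation.

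That first set of settings was RLE size factors, library totals, no filter on low counts, DESeq2 1.42.0, limma-voom, a minimum of 1000 UMIs, equal numbers of nuclei, no context term, hemispheres as replicates, and each library left out in turn. Added after seeing the data were a doublet score of at most 0.05, glial nuclei without those over 2% neuronal RNA, shares without clusters taken as neighbouring tissue, and the neuron subsets. The clusters taken as neighbouring tissue were choroid plexus, fibroblasts, the mixed neurons and inhibitory clusters 2, 5 and 7. Whether they lie outside the hippocampus was not tested. Neuronal RNA was the share of UMIs from 200 genes with at least 50 CPM in excitatory neurons and low levels in glia. The edgeR and camera steps were tested on simulated counts with 200 changed genes, each with a mean count of at least 20. Every gene took the spread that edgeR fitted for genes of its level. Libraries differed only in their totals and in the planted changes. The recovered shares are therefore not a measure of power in the real libraries. Among genes changed 2-fold, the share recovered for VEGFC against GFP was 89% of 100 in astrocytes (12883 genes simulated), 95% in excitatory neurons (16468), 85% in microglia (2093), 89% in oligodendrocytes (8025) and 81% in fibroblasts (2789). For TBI against sham it was 85%, 86%, 72%, 72% and 66% in the same classes. Of the simulated genes without a change, 4 to 9 were called per class for VEGFC and 6 to 11 for TBI. A simulated list of 30 genes raised 1.5-fold had an adjusted p of at most 0.000226 in camera with the preset correlation. With an estimated one it was 0.166 to 0.982, so with 2 residual degrees of freedom the estimated correlation missed a list that was changed. The simulated genes were drawn independently of each other. The simulation therefore cannot say how the preset correlation performs where genes vary together. The estimated setting missed the raised list in every simulated class. A list that does not pass with it may be changed or unchanged, and its adjusted p cannot decide between these. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.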

Results

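Single-nucleus RNA was measured in hippocampi of male PS19 mice, which carry a mutant human tau transgene and are used as a model of tau pathology. Mice had a sham operation or a controlled cortical impact on the right side, a mild traumatic brain injury (TBI), and were given an adeno-associated virus (AAV) coding for GFP or for VEGFC, a growth factor for lymphatic vessels. The 6 libraries were 1 each of sham GFP right, sham VEGFC right, TBI GFP right, TBI GFP left, TBI VEGFC right and TBI VEGFC left hippocampus. The deposited files held 28650 nuclei, 3676 to 6002 per library, with 15358208 to 18379148 unique molecular identifier (UMI) counts per library and a median of 2689 to 3704 UMIs per nucleus. No combination of injury, vector and side was repeated, so no single difference between 2 libraries has a replicate check. The vector contrast was made in 3 contexts (sham right, TBI right and TBI left). P-values weigh how far these libraries disagree together with a spread that edgeR borrows from the other genes of a class. The borrowed part had a median of 7.5 prior degrees of freedom in inhibitory neurons, 72.4 in astrocytes and 8062.4 in oligodendrocytes, against 2 residual ones. It was infinite in choroid plexus and fibroblasts. In classes with high values, a small p-value says little about how well the libraries agree on that gene. The labels do not say how many mice entered a library or whether left and right libraries came from the same mice.

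The authors named 9 classes in 32 clusters. Excitatory neurons made up 43.4% of nuclei, astrocytes 19.9%, inhibitory neurons 15.3%, oligodendrocytes 7.89%, choroid plexus epithelium 4.52%, oligodendrocyte precursors (OPC) 3.47%, a mixed neuron class 2.73%, fibroblasts 1.44% and microglia 1.42%. Excitatory cluster 1 had the pyramidal markers Gpr161 and Fibcd1 among its 10 leading genes and is called CA1-like. Excitatory clusters 2 and 3 had Plk5, Stxbp6, Trpc6, Dsp and Prox1 and are called dentate granule-like, and excitatory cluster 4 had Grik4, Nectin3, Cpne4 and Galnt3 and is called CA3-like. Inhibitory clusters 1, 3, 6 and 8 form an interneuron subset, led by genes such as Lhx6, Vip, Lamp5 and Reln. Excitatory cluster 7 was led by Dcn, a fibroblast marker. Inhibitory clusters 2 and 7 had Igfbpl1 and Foxp2, listed as markers of other classes, among their 10 leading genes. None of these 3 clusters had a listed marker of its own class there, and neither did inhibitory clusters 1 and 5. The inhibitory list was still the highest in inhibitory clusters 1, 5 and 7, at mean log2 folds of 1.55, 0.19 and 0.71. Neurons are therefore described first through these subsets of clusters, which were chosen after seeing the data, and the 2 broad neuron classes follow.

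Microglia were 3.75% of nuclei in TBI VEGFC left (exact binomial 95% interval 3.16 to 4.42) and 0.70% to 1.72% in the other 5 libraries. The log2 ratio of their share, VEGFC over GFP, was -1.29 in sham right, 0.57 in TBI right and 2.35 in TBI left, so its direction differed between contexts. Choroid plexus epithelium was the only class with the same direction in all 3 contexts, at -0.33, -0.70 and -0.13, a mean of -0.39 (exact two-sided sign-flip permutation p = 0.25, the smallest that 3 contexts allow). Oligodendrocytes ranged from 5.21% in sham VEGFC right to 11.7% in TBI VEGFC left. At the level of clusters, 7 of 32 had the same vector direction in all 3 contexts, where 8 would have it by chance.

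**Figure D1:**
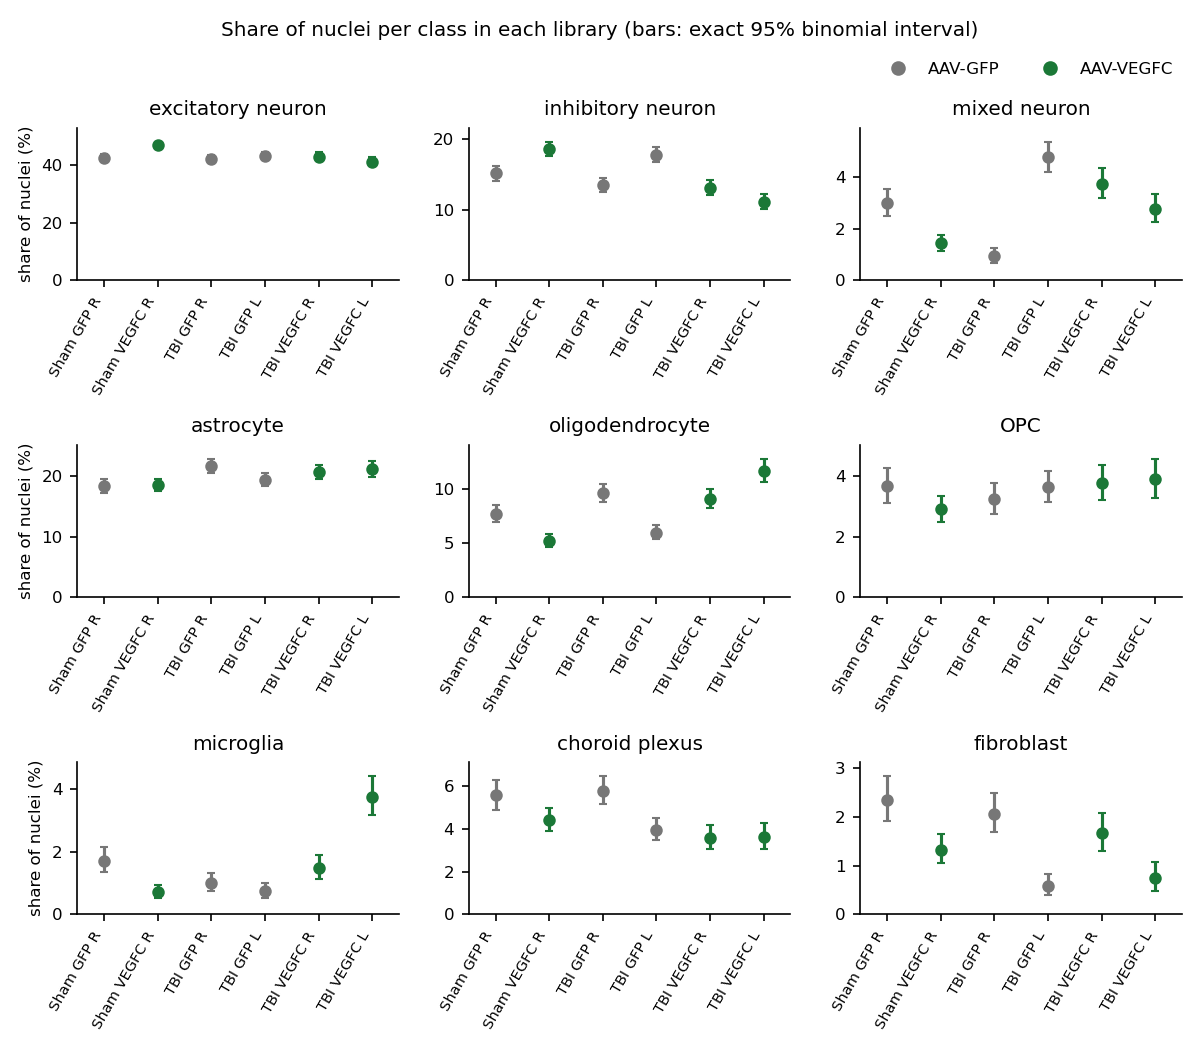
Share of nuclei in percent (vertical axis) for each of the 9 classes in the 6 libraries (horizontal axis; R right, L left), grey for AAV-GFP and green for AAV-VEGFC, with exact 95% binomial intervals that cover counting error only. Microglia reached 3.75% in TBI VEGFC left, and mixed neurons ranged from 0.929% to 4.77%.

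Some clusters also varied in share between libraries. Inhibitory cluster 5, led by Drd2, Penk and Rgs9, genes known from striatal projection neurons, was 3.74% of nuclei in TBI GFP left (exact 95% interval 3.25 to 4.28), 0.0544% in TBI VEGFC left and 0.343% to 1.5% elsewhere. Excitatory cluster 7 ranged from 0.514% to 3.13%. Despite Dcn, its highest list of cell type markers was that of CA1 pyramidal neurons, at a mean log2 fold of 0.29 over all other nuclei. The mixed neuron class, led by Glra3, Baiap3 and Slc17a6, ranged from 0.929% in TBI GFP right to 4.77% in TBI GFP left.

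The delivered gene did not differ detectably between vectors. Vegfc, on chromosome 8 from 54077606 to 54187096 in mm10, stood at 10.2 to 10.9 CPM (UMIs of the gene scaled to a common library total) in all 6 libraries, on 156 to 200 UMIs each, with exact Poisson intervals that overlap. Whether transcripts of the vector would be counted under this gene is not given in the sources used here. Its levels were 30.4 to 83.5 CPM in fibroblasts with at least 3 UMIs and 20.2 to 35.2 CPM in choroid plexus epithelium. Of the VEGF receptors, Flt4, which binds VEGFC, had 2 to 7 UMIs per library, and Kdr had 5 to 21. Flt1 stood at 2.95 to 6.58 CPM over all nuclei and at 102 to 273 CPM in fibroblasts. Mouse Mapt, the endogenous tau gene, stood at 282 to 351 CPM over all nuclei and at 1504 to 1929 CPM in oligodendrocytes. None of these intervals covers variation between mice.

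The first comparison asked what AAV-VEGFC changed against AAV-GFP across the 3 contexts. In oligodendrocytes, Tgfbr2, a receptor of TGF-beta (chromosome 9, 116084293 to 116175360), was higher with VEGFC by 0.96 on the log2 scale (SE 0.20, adjusted p = 0.00192), at 46.5 to 76.5 CPM in the GFP libraries and 102.5 to 125 CPM in the VEGFC libraries. Hsp90aa1, a cytosolic chaperone, was higher by 0.71 (SE 0.16, adjusted p = 0.0136) and Fcho1, of endocytosis, by 0.61 (SE 0.15, adjusted p = 0.043). Tnni1, a troponin subunit, fell by 1.62 (SE 0.26, adjusted p = 7.34e-06), from 48.9 to 88.8 CPM with GFP to 19.0 to 31.7 CPM with VEGFC. Tubb3, a tubulin of neurons, was lower by -1.16 (SE 0.24, adjusted p = 0.00192). In astrocytes, the phosphodiesterase gene Pde10a was higher by 0.73 (SE 0.12, adjusted p = 0.000227) and Ccdc61 by 1.09 (SE 0.24, adjusted p = 0.0356). Mamdc2 was lower in astrocytes by -0.76 (SE 0.14, adjusted p = 0.00119). Each of these genes had the same direction in all 3 contexts. DESeq2 called none of these 8 (0 in either class, with 19 and 58 genes at an unadjusted p under 0.05). Leaving out 1 library ended each call: replicate 3 or 5 for Tnni1, 3 to 6 for Tgfbr2, Tubb3 and Mamdc2, 4 to 6 for Pde10a, 1, 2, 3 or 5 for Ccdc61, and any of the 6 for Hsp90aa1 and Fcho1.

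**Figure D2:**
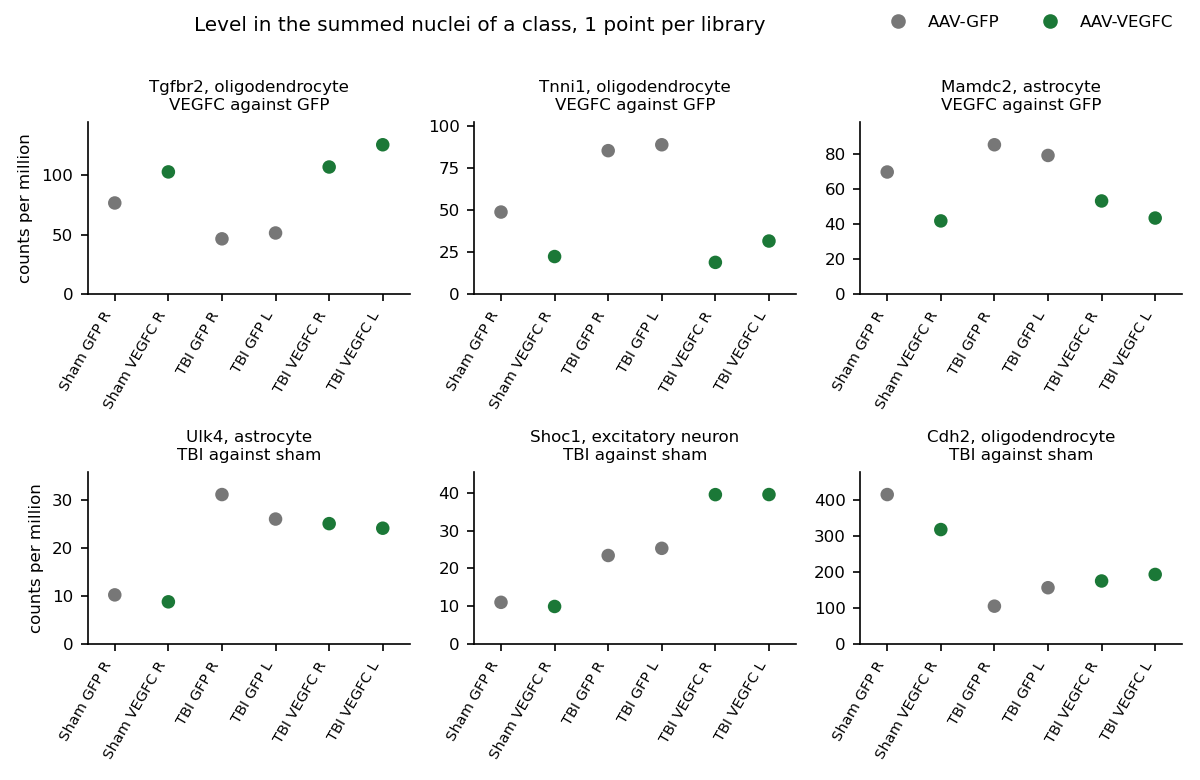
Levels in CPM (vertical axis) of 6 genes in the summed nuclei of the class named above each panel, 1 point per library, grey for AAV-GFP and green for AAV-VEGFC. Tgfbr2 lay at 102.5 to 125 in VEGFC libraries and 46.5 to 76.5 in GFP libraries, and Cdh2 at 105.5 to 193 in TBI libraries against 318 and 414.5 in sham.

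In oligodendrocytes Fam155a was also higher, by 1.73 (SE 0.33, adjusted p = 0.000864), with 22.1% of its UMIs from 1 nucleus and a level of 2093 CPM in excitatory neurons. Trpm3 was lower by -1.40 (SE 0.30, adjusted p = 0.00399), with 43.3% of its UMIs from 1 nucleus and a level of 725.5 CPM in excitatory neurons. Adam11 fell by 0.65 (SE 0.13, adjusted p = 0.00192) but did not move the same way in every context. It is named after its values were seen. In microglia, Galntl6, Snhg11 and Lsamp were past the threshold in the lower direction, with 41.2% to 64.9% of their UMIs from 1 nucleus, and none had the same direction in every context. In fibroblasts the only gene was Pde10a, higher by 1.89 (SE 0.28, adjusted p = 6.4e-08), again without the same direction in every context.

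Neuron subsets held few vector genes. In CA1-like neurons Kirrel3, a cell adhesion gene, was higher by 0.60 (SE 0.10, adjusted p = 0.00772), Zfpm2 by 0.55 (SE 0.10, adjusted p = 0.0203), Trpm3 by 0.79 (SE 0.16, adjusted p = 0.0404) and Cpsf4l by 0.98 (SE 0.20, adjusted p = 0.0404). Zfp46 fell by 1.19 (SE 0.19, adjusted p = 0.00561). In dentate granule-like neurons Zfp804b was higher by 0.72 (SE 0.12, adjusted p = 0.00995). March1, a ubiquitin ligase, fell by 0.74 (SE 0.12, adjusted p = 0.00507), with a level of 212 CPM in sham GFP against 73.5 to 102 CPM in the other 5 libraries. In the interneuron subset Chsy3 rose by 0.50 (SE 0.09) and Pde10a by 0.33 (SE 0.07), and the channel gene Ano3 and the cadherin Cdh9 fell by 0.57 (SE 0.12) and 0.48 (SE 0.09). Of the 21 vector calls named by rule, these subsets included, 14 were kept with library totals and 0 with DESeq2. Without replicate 3 or 5, 5 and 4 of them were kept. CA3-like neurons had 0 genes past the threshold with edgeR, with 629 of 10335 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The broad excitatory class had 0 with edgeR, DESeq2 and limma-voom, with 1077 of 16468 genes at an unadjusted p under 0.05 in edgeR. The inhibitory class had 0 by each of the 3 tools, with 593 at an unadjusted p under 0.05, the mixed class 0 with 399, and OPC 0 with 357. These counts of 0 depend on the filter on low counts. Without it edgeR gave 65 higher and 62 lower genes in excitatory neurons, 13 and 47 in inhibitory neurons, 4 and 2 in mixed neurons, 3 and 2 in CA3-like neurons and 0 and 1 in OPC. With library totals it gave 0 higher and 2 lower in CA3-like neurons and 0 and 1 in OPC. The genes nearest the threshold in the lower direction were Cux2 at -0.69, Npas1 at -0.79, Egr1 at -0.86 and Zfp46 at -0.77 in excitatory neurons (adjusted p = 0.153 each) and Meg3 at -0.49 in astrocytes (adjusted p = 0.0626). None passed.

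Over the 9 classes, 13 gene and class pairs were higher and 10 lower with VEGFC among 81848 tested. With TMM factors, 4425 of the 81848 pairs had an unadjusted p under 0.05 in edgeR, where 4092 would be expected without any change. With library totals in place of TMM factors the split was 10 higher and 13 lower. DESeq2 gave 0 over the same pairs, with 420 at an unadjusted p under 0.05, and the edgeR count was 290 without replicate 1 (sham GFP) and 390 without replicate 2 (sham VEGFC).

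**Figure D3:**
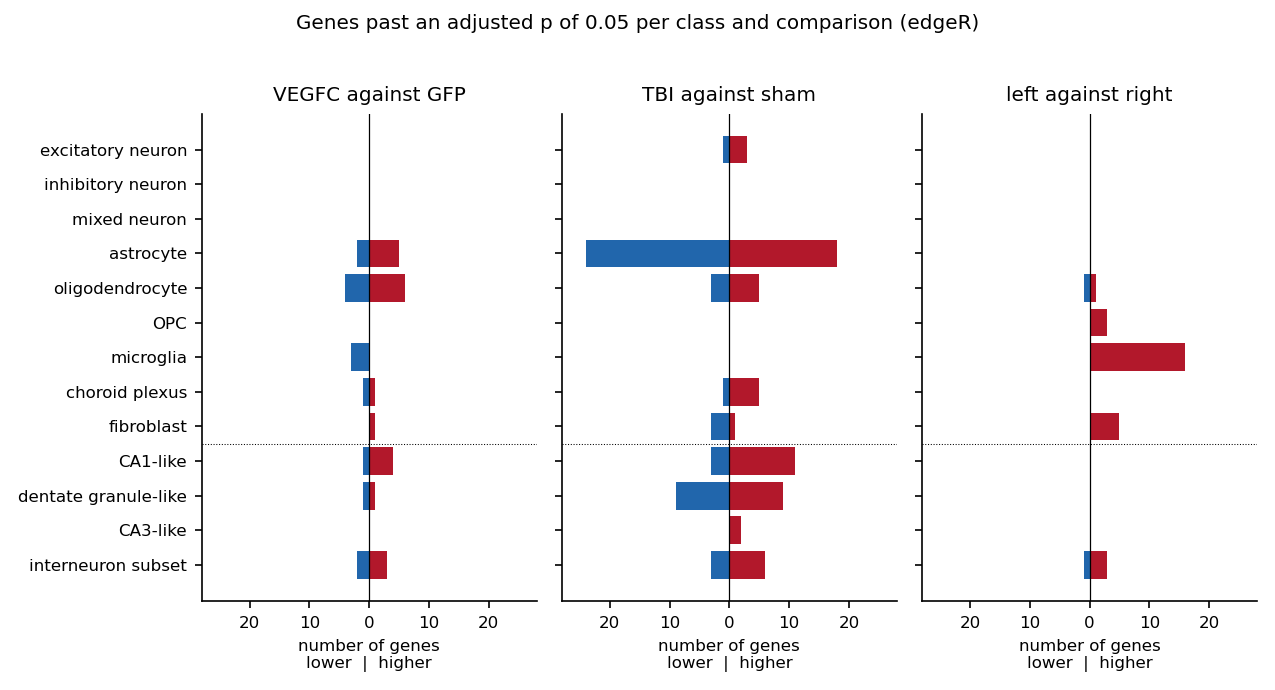
Number of genes past an adjusted p of 0.05 in edgeR (horizontal axis; red higher, blue lower) for each class and, under the dotted line, each neuron subset, in the 3 comparisons. Astrocytes had 18 higher and 24 lower for TBI against sham, and microglia 16 higher for left against right.

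Gene lists fixed before the data were examined were compared with all other genes by camera, and 19 of 217 class and list tests passed for the vector. The type I interferon list was higher with VEGFC in astrocytes, with 18 of 19 members on that side and a median log2 fold of 0.26 (adjusted p = 1.4e-08). With an estimated correlation that adjusted p was 0.762. Over all genes 0 members passed in edgeR, and 7 did adjusted over the list alone. Usp18 was at 1.07 (SE 0.25) and Parp14 at 0.71 (SE 0.24). The fibroblast interferon list went the other way, with 6 of 7 members lower and a median of -0.60 (adjusted p = 0.0233; adjusted p = 0.748 with an estimated correlation). The unfolded protein response list, of chaperones and folding enzymes of the endoplasmic reticulum, was higher in choroid plexus with 15 of 18 members up (adjusted p = 2.84e-06), in excitatory neurons with 16 of 20 (adjusted p = 0.00445), in OPC with 10 of 13 (adjusted p = 0.0118) and in microglia with 7 of 9 (adjusted p = 0.0347). With an estimated correlation these adjusted p were 0.985, 0.95, 0.72 and 0.564. Its chaperone Hsp90b1 stood at 0.59 (SE 0.14) in choroid plexus and 0.26 (SE 0.08) in excitatory neurons, and neither passed over all genes. Adjusted over the list alone, 1, 0, 2 and 1 members passed in these 4 classes, against 0 over all genes in each.

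Cytosolic heat shock genes were higher in oligodendrocytes, with 10 of 14 up and a median of 0.40 (adjusted p = 2.28e-05; adjusted p = 0.991 with an estimated correlation). Hsp90aa1 passed over all genes, and 2 members did adjusted over the list alone. Immediate early genes were lower in excitatory neurons, with 16 of 24 down and Egr1 at -0.86 (SE 0.125), Ier2 at -1.22 (SE 0.22) and Junb at -0.49 (SE 0.10) (adjusted p = 0.000244; adjusted p = 0.95 with an estimated correlation). Over all genes 0 of them passed, and 5 did adjusted over the list alone. The list was not past the threshold in the subsets, with 10 of 15 members down and a median of -0.12 in dentate granule-like neurons (adjusted p = 0.0568), 12 of 17 down and a median of -0.31 in CA3-like neurons (adjusted p = 0.176) and 16 of 23 up and a median of 0.09 in CA1-like neurons (adjusted p = 0.48). Cortical marker genes were lower in the same class, with 8 of 10 down (adjusted p = 0.00169; adjusted p = 0.95 with an estimated correlation), and so were cholesterol synthesis genes with 19 of 24 down (adjusted p = 0.00169; adjusted p = 0.95 with an estimated correlation). Adjusted over the list alone 1 cortical and 0 cholesterol genes passed, and 0 of either did over all genes. Immediate early genes were also lower in astrocytes (11 of 13 down, adjusted p = 0.00737), as were p53 target genes (11 of 12 down, adjusted p = 0.00737), mitochondrially encoded transcripts (10 of 12 down, adjusted p = 0.00265) and ribosomal protein genes (50 of 73 down, adjusted p = 0.0267). With an estimated correlation these adjusted p were 0.762, 0.762, 0.762 and 0.993. Adjusted over the list alone 1, 0, 2 and 0 of their members passed, and 0 over all genes.

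Myelin genes were lower in OPC, with 11 of 13 down (adjusted p = 0.000157; adjusted p = 0.72 with an estimated correlation), and Mbp at -0.97 (SE 0.21) had 13.7% of its UMIs from 1 nucleus. 3 members passed adjusted over the list alone and 0 over all genes. In the mixed neurons ribosomal protein genes (57 of 72 down, adjusted p = 0.00871) and oxidative phosphorylation genes (34 of 48 down, adjusted p = 0.0103) were lower, both with an adjusted p = 0.828 with an estimated correlation and 0 members past either adjustment. In fibroblasts 4 of 5 tested VEGF ligand and receptor genes were higher, with Nrp1 at 1.14 (SE 0.50) and Nrp2 at 1.16 (SE 0.56) (adjusted p = 0.0233; adjusted p = 0.748 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. In microglia the disease-associated oligodendrocyte list, here with B2m, H2-D1 and Cd63, had 6 of 6 members higher (adjusted p = 0.015; adjusted p = 0.564 with an estimated correlation) and 0 past either adjustment. In the neuron subsets, mitochondrially encoded transcripts were lower in CA3-like neurons (10 of 10 down, adjusted p = 1.06e-05; adjusted p = 0.939 with an estimated correlation), and the unfolded protein response list was higher in dentate granule-like neurons (17 of 20 up, adjusted p = 8.67e-05; adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone 6 and 2 members passed, and 0 over all genes. Lists nearest to tau and gliosis did not pass. Tau and its kinases had median folds of 0.01 in CA1-like neurons (adjusted p = 0.752) and -0.01 in dentate granule-like neurons (adjusted p = 0.916), disease-associated microglia genes 0.08 in microglia (adjusted p = 0.283), homeostatic microglia genes 0.01 (adjusted p = 0.652) and reactive astrocyte genes -0.05 (adjusted p = 0.993).

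The second comparison asked what TBI changed in the right hippocampus against sham. Ulk4, a kinase-like gene (chromosome 9, 120955351 to 121277197), was higher after TBI in astrocytes by 1.55 (SE 0.29, adjusted p = 0.00166), from 8.82 and 10.3 CPM in sham to 25.1 and 31.1 CPM in TBI right. It was also higher in dentate granule-like neurons by 1.01 (SE 0.16, adjusted p = 0.000944), in CA1-like neurons by 0.85 (SE 0.13, adjusted p = 0.000785) and in the broad excitatory class by 0.86 (SE 0.10, adjusted p = 0.0198). Shoc1, a meiotic recombination gene that is also a leading gene of excitatory cluster 1, was higher in CA1-like neurons by 1.65 (SE 0.16, adjusted p = 1.15e-08), from 30.1 and 32.1 CPM to 70.1 and 126 CPM. Cdh2, the N-cadherin gene (chromosome 18, 16588877 to 16809246), fell in oligodendrocytes by 1.42 (SE 0.17, adjusted p = 1.75e-13), from 318 and 414.5 CPM to 105.5 and 175 CPM. Car10 was higher in choroid plexus by 1.43 (SE 0.19, adjusted p = 2.41e-10). The calls of Cdh2 in oligodendrocytes and Ulk4 in excitatory neurons held in all 16 and 15 other settings run on them, DESeq2 and the removal of each library included. That of Ulk4 in astrocytes was lost with DESeq2 and without replicate 3 or 5, and that of Car10 with DESeq2 and without replicate 2, 3 or 5.

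Astrocytes had the most genes past the threshold for TBI, 18 higher and 24 lower, and DESeq2 gave 0 there, with 103 at an unadjusted p under 0.05. Tnr, a matrix glycoprotein, was higher by 0.88 (SE 0.19, adjusted p = 0.0111), Dalrd3 by 0.72 (SE 0.18, adjusted p = 0.038) and Adamtsl3 by 0.72 (SE 0.18, adjusted p = 0.0497). Of 16 other settings, the calls of Tnr, Dalrd3 and Adamtsl3 held in 10, 8 and 6. Hpse2 was higher by 3.60 (SE 0.64, adjusted p = 0.000478), with 26.1% of its UMIs from 1 nucleus and 39.5 CPM in TBI VEGFC right against 1.51 CPM in TBI GFP right, and without replicate 5 (TBI VEGFC right) its fold was -0.20. Iigp1, an interferon-induced GTPase with close paralogs, fell by 1.91 (SE 0.31, adjusted p = 0.000261). The other named genes that fell in astrocytes were March1 at -1.86, Lrfn5 at -1.37, Ralyl at -1.28, Nrg3 at -1.27, Mctp1 at -1.23, Pbx3 at -1.23, Cntn4 at -1.20 and Epha6 at -1.15, with adjusted p from 0.000261 to 0.0497. Their calls held in 7 (Lrfn5) to 12 (Cntn4) of 16 other settings. In excitatory neurons Pbx3 stood at 29.3 CPM and the other 7 at 462 to 4370 CPM, and in astrocytes the 8 genes stood at 12 to 45.9 CPM, with 20.7% of the UMIs of Epha6 from 1 nucleus. Neuronal RNA, the share of 200 genes high in excitatory neurons, was 0.379% and 0.373% of astrocyte UMIs in sham and 0.298% and 0.312% in TBI right. Without the 9 of 5692 astrocytes that had over 2% neuronal RNA, an alternative chosen after seeing the data, 12 genes were higher and 8 lower.

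In oligodendrocytes Luzp2 was higher by 0.93 (SE 0.20, adjusted p = 0.00959), Cdk8 by 0.73 (SE 0.15, adjusted p = 0.00248), Arid5b by 0.74 (SE 0.18, adjusted p = 0.0372) and Ppp2r2c by 1.02 (SE 0.25, adjusted p = 0.0427). Tubb3 was lower by -1.47 (SE 0.27, adjusted p = 0.000315). Of 16 other settings, the calls of Luzp2, Cdk8 and Tubb3 held in 13 each, that of Arid5b in 7 and that of Ppp2r2c in 4. In choroid plexus Id3, a transcriptional regulator, fell by 0.86 (SE 0.16, adjusted p = 0.000313), Tmem108 rose by 0.48 (SE 0.11, adjusted p = 0.0198) and Slc6a20a rose by 0.69 (SE 0.16, adjusted p = 0.0296). In fibroblasts H2-D1, a class I histocompatibility gene whose reads can be shared with related genes, fell by 2.535 (SE 0.56, adjusted p = 0.0062), Pde10a fell by 1.74 (SE 0.34), Meg3 fell by 1.63 (SE 0.36) and Nnat rose by 0.99 (SE 0.24), of which only H2-D1 moved the same way with both vectors. For Meg3 46.7% of the UMIs were from 1 nucleus. The call of H2-D1 held in 6 of 13 other settings. The genes other than H2-D1 in fibroblasts and Car10 in choroid plexus are named after their values were seen.

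In dentate granule-like neurons 9 genes were higher and 9 lower after TBI. Disc1, a scaffold gene that is also a leading gene of excitatory cluster 3, was higher by 0.97 (SE 0.15, adjusted p = 0.000939), the peptide transporter Slc15a2 by 1.01 (SE 0.22, adjusted p = 0.0484) and the chaperone Hsp90b1 by 0.58 (SE 0.11, adjusted p = 0.014). Tek, the angiopoietin receptor gene, fell by 1.23 (SE 0.19, adjusted p = 0.000944), from 32.3 and 43.8 CPM to 14.8 and 17.3 CPM, and it also fell in the broad excitatory class by 1.05 (SE 0.12, adjusted p = 0.0198). Phldb2 at -1.47, Dpp10 at -0.80, Rad51ap2 at -0.78, March1 at -0.70 and Gabrg3 at -0.60, a GABA receptor subunit, were the other named genes that fell. March1 went from 212 to 101.5 CPM with GFP and from 85.7 to 73.5 CPM with VEGFC, so its fall rests mainly on the sham GFP library. In CA1-like neurons, with 11 genes higher and 3 lower, Slc2a9 was higher by 0.74, Pard3 by 0.71, Prrt1 by 0.56 and Col11a1 by 0.49. The clock-related gene Ciart fell by 1.11 (SE 0.21, adjusted p = 0.0143), Cntn5 by 0.71 and Lingo2 by 0.60. In the interneuron subset Pex3 was higher by 0.75 and the muscarinic receptor Chrm2 by 0.69 (SE 0.14, adjusted p = 0.00566). Tafa1 fell by 0.97, Slit2 by 0.63 and Fhit by 0.61. Of the 48 TBI calls named by rule, those of the subsets included, 36 were kept with library totals and 4 with DESeq2. CA3-like neurons had 2 higher genes, both gene models with clone names. The one with the larger fold, 1.16 (SE 0.12), was also past the threshold and higher in 4 classes. Its folds were 0.48 in astrocytes, 0.56 in choroid plexus, 0.87 in excitatory neurons and 0.94 in oligodendrocytes. In the CA1-like, dentate granule-like and interneuron subsets it was past the threshold at 0.99, 0.56 and 0.82. Whether so widely shared a rise reflects injury or another difference between the libraries was not tested. The inhibitory class, mixed neurons, OPC and microglia had 0 by edgeR, DESeq2 and limma-voom, with 522, 302, 362 and 127 genes at an unadjusted p under 0.05 in edgeR. Without the filter on low counts edgeR gave 8 higher and 13 lower genes in the inhibitory class, 2 and 1 in mixed neurons, 0 and 4 in OPC and 0 and 0 in microglia, and with library totals OPC had 1 lower gene.

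Over the 9 classes, 32 gene and class pairs were higher and 32 lower after TBI, and DESeq2 gave 4 and 3. Of 81848 pairs, 4118 had an unadjusted p under 0.05 in edgeR, where 4092 would be expected without any change. The TBI over sham folds with GFP and with VEGFC were also correlated, over genes with at least 100 counts in each library. The correlation ranged from -0.606 in mixed neurons to 0.098 in CA1-like neurons, with -0.027 in excitatory neurons and 0.056 in astrocytes. Fibroblasts and microglia had too few such genes. The total of 64 became 191 without replicate 1, 145 without replicate 2, 117 without replicate 4 (TBI GFP left) and 120 without replicate 6 (TBI VEGFC left), and 17 with equal numbers of nuclei in each library. Of the 48 calls named by rule, subsets included, 11 were kept without replicate 5 and 46 without replicate 4 or 6. Replicates 4 and 6 are left libraries and enter this comparison mainly through the shared spread, so the 46 say little.

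The interferon list was lower after TBI in astrocytes, with 14 of 19 members down and a median of -0.40 (adjusted p = 1.45e-05; adjusted p = 0.822 with an estimated correlation), with Ifit3 at -0.70 (SE 0.24) and Ddx60 at -0.45 (SE 0.16). It was lower in fibroblasts with 7 of 7 down (adjusted p = 5.92e-05; adjusted p = 0.619 with an estimated correlation) and higher in choroid plexus with 5 of 5 up (adjusted p = 0.00155; adjusted p = 0.941 with an estimated correlation). Over all genes 0 members passed in each class, and 0, 2 and 3 did adjusted over the list alone. Class I antigen presentation genes were lower in astrocytes (8 of 10 down, adjusted p = 0.0457; adjusted p = 0.822 with an estimated correlation), and homeostatic astrocyte genes higher (13 of 16 up, adjusted p = 0.0385; adjusted p = 0.822 with an estimated correlation). With library totals these adjusted p were 0.0626 and 0.102. Glutamate receptor genes were lower in astrocytes (16 of 19 down, adjusted p = 0.0213; adjusted p = 0.822 with an estimated correlation), with Grm5 falling by 0.41 (SE 0.10, adjusted p = 0.0497). Disease-associated oligodendrocyte genes were lower too (11 of 13 down, adjusted p = 0.00832; adjusted p = 0.822 with an estimated correlation), with the tetraspanin Cd9 falling by 0.46 (SE 0.11, adjusted p = 0.035). Of these 4 astrocyte lists, 1, 0, 1 and 1 members passed adjusted over the list alone, and 0, 0, 1 and 1 over all genes.

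Mitochondrially encoded transcripts were higher after TBI in excitatory neurons (12 of 13 up, adjusted p = 0.0057), mixed neurons (10 of 10, adjusted p = 1.59e-06), oligodendrocytes (9 of 10, adjusted p = 0.00889) and microglia (6 of 7, adjusted p = 0.0325). With an estimated correlation these adjusted p were 0.985, 0.952, 0.889 and 0.597, and 0 members passed either over all genes or adjusted over the list alone. In dentate granule-like neurons 11 of 13 were up (adjusted p = 1.06e-08; adjusted p = 0.998 with an estimated correlation), with 7 past the threshold adjusted over the list alone and 0 over all genes. The median share of mitochondrial UMIs per nucleus was 0.0826% to 0.11% over the 6 libraries, with 0.0949% and 0.0826% in sham and 0.11% and 0.095% in TBI right. The unfolded protein response list was higher in choroid plexus (13 of 18 up, adjusted p = 0.00266; adjusted p = 0.941 with an estimated correlation), excitatory neurons (14 of 20, adjusted p = 0.0298; adjusted p = 0.985 with an estimated correlation) and dentate granule-like neurons (14 of 20, adjusted p = 0.000573; adjusted p = 0.998 with an estimated correlation). Adjusted over the list alone 2, 0 and 2 members passed, and 0, 0 and 1 over all genes. In oligodendrocytes heat shock genes (13 of 14 up, adjusted p = 0.00797) and ribosomal protein genes (56 of 73 up, adjusted p = 0.00889) were higher, both with an adjusted p = 0.889 with an estimated correlation. 1 and 0 members passed adjusted over the list alone and 0 over all genes. In OPC the differentiating precursor list was lower, with 8 of 10 down, Tcf7l2 at -0.79 (SE 0.19) and Fyn at -0.62 (SE 0.18) (adjusted p = 0.00466; adjusted p = 0.8 with an estimated correlation), 2 past adjusted over the list alone and 0 over all genes. Matrix genes were higher in the interneuron subset (11 of 11 up, adjusted p = 0.00318; adjusted p = 0.981 with an estimated correlation), with Col5a2 at 0.52 (SE 0.16), 1 past adjusted over the list alone and 0 over all genes. Cortical marker genes were lower in excitatory neurons (6 of 10 down, adjusted p = 0.0243; adjusted p = 0.985 with an estimated correlation), with 1 gene past adjusted over the list alone and 0 over all genes. Disease-associated and homeostatic microglia genes did not pass in microglia (adjusted p = 0.342 and 0.0886), nor did reactive astrocyte genes in astrocytes (adjusted p = 0.628), myelin genes in oligodendrocytes (adjusted p = 0.793) or tau and its kinases in CA1-like neurons (adjusted p = 0.582).

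The third comparison set the left hippocampus, opposite the impact, against the right after TBI. It shares the TBI right libraries with the second comparison, so opposite signs in these comparisons are not independent. In the interneuron subset Tafa1, a secreted chemokine-like gene, was higher on the left by 1.04 (SE 0.20, adjusted p = 0.00467), the splicing gene Snrpf by 0.98 (SE 0.19, adjusted p = 0.00467) and mt-Nd3 by 0.81 (SE 0.18, adjusted p = 0.0489). Tafa1 fell by 0.97 in the same subset for TBI against sham, so its calls are not separate findings. Hapln1, a link protein of the matrix and a leading gene of inhibitory cluster 6, fell by 0.64 (SE 0.14, adjusted p = 0.0489). In OPC the netrin receptor Unc5d was higher by 2.24 (SE 0.44, adjusted p = 0.0454), with 21.7% of its UMIs from 1 nucleus, and in oligodendrocytes Chsy3 by 1.20 (SE 0.27, adjusted p = 0.0417). Unc5d and Chsy3 are named after their values were seen. In fibroblasts Gpc5 was higher by 3.74 (SE 0.56, adjusted p = 3.86e-08) and Asic2 by 3.61 (SE 0.74, adjusted p = 0.000729), with 33.3% and 30% of their UMIs from 1 nucleus, on 32 and 27 nuclei in the left libraries. CA1-like, CA3-like and dentate granule-like neurons had 0 genes by edgeR, DESeq2 and limma-voom, with 427, 411 and 396 at an unadjusted p under 0.05 in edgeR. Without the filter on low counts the edgeR counts were 0 in CA1-like, 2 higher and 3 lower in CA3-like, and 1 higher in dentate granule-like neurons.

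In microglia 16 genes were higher on the left and 0 lower, among them Galntl6, Dlg2, Adgrb3, Ank3, Ptprd, Pcdh9, Adgrl3, Cacna2d1, Lrp1b and Lsamp, with log2 folds from 3.15 to 8.69. These 10 genes stood at 646 to 6759 CPM in excitatory neurons. Of the 16, 15 had 28.6% to 77.7% of their UMIs from 1 nucleus, and for Dlg2 that share was 57.9%. Neuronal RNA was 1.33% and 0.958% of microglial UMIs in the left libraries and 0.393% and 0.387% in the right ones, and 0.394% and 0.447% on the left without 1 nucleus in each left library. Without these and 1 further microglial nucleus, which had over 2% neuronal RNA, edgeR gave 0 higher and 0 lower genes, with 84 of 2122 at an unadjusted p under 0.05. In the full set of microglia DESeq2 gave 1 higher gene and limma-voom 4 higher and 1 lower.

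Over the 9 classes, 25 gene and class pairs were higher and 1 lower on the left, and DESeq2 gave 3 and 0. Of 81848 pairs, 2860 had an unadjusted p under 0.05 in edgeR, where 4092 would be expected without any change. The left over right folds with GFP and with VEGFC were also correlated, over genes with at least 100 counts in each library. The correlation ranged from -0.244 in inhibitory neurons to 0.172 in OPC, with -0.143 in excitatory neurons and -0.019 in astrocytes. Fibroblasts and microglia had too few such genes. In the lower direction the pairs nearest the threshold were Pdrg1 at -1.96 and Slc6a20a at -0.62 in choroid plexus, Hdgfl3 at -0.905 and Slco1a4 at -3.32 in oligodendrocytes and Stk32a at -0.89 in astrocytes (adjusted p from 0.0533 to 0.753). Astrocytes, choroid plexus, excitatory, inhibitory and mixed neurons had 0 genes by edgeR, DESeq2 and limma-voom, with 517, 347, 369, 448 and 262 at an unadjusted p under 0.05 in edgeR. Without the filter on low counts edgeR gave 32 higher and 14 lower genes in inhibitory, 4 and 1 in excitatory and 4 and 0 in mixed neurons, and 0 in astrocytes and choroid plexus. The total of 26 became 54 without replicate 1, 79 without replicate 2, 113 without replicate 4 and 277 without replicate 6.

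Differentiating precursor genes were higher on the left in OPC, with 10 of 10 up, Bcas1 at 0.53 (SE 0.14) and Fyn at 0.60 (SE 0.18) (adjusted p = 8.73e-09; adjusted p = 0.472 with an estimated correlation), 4 past adjusted over the list alone and 0 over all genes. The same list was lower for TBI against sham, and both contrasts use the TBI right libraries, so the opposite signs are not independent. In OPC ribosomal protein genes (50 of 70 down, adjusted p = 0.00127; adjusted p = 0.55 with an estimated correlation) and lysosomal genes (15 of 20 down, adjusted p = 0.0454; adjusted p = 0.472 with an estimated correlation) were lower and glutamate receptor genes higher (10 of 16 up, adjusted p = 0.0277; adjusted p = 0.472 with an estimated correlation), with Grin2a at 20.8% of its UMIs from 1 nucleus. Interferon genes were higher on the left in astrocytes (17 of 19 up, adjusted p = 2.71e-05; adjusted p = 0.913 with an estimated correlation) and fibroblasts (6 of 7 up, adjusted p = 0.00363; adjusted p = 0.52 with an estimated correlation) and lower in excitatory neurons (15 of 17 down, adjusted p = 0.0197; adjusted p = 0.903 with an estimated correlation). Over all genes 0 members of these lists passed, and 1 in astrocytes, 1 in fibroblasts and 0 in the other 4 did adjusted over the list alone. In astrocytes and fibroblasts the interferon list was lower for TBI against sham, so its opposite signs there are not independent either. Mitochondrially encoded transcripts were higher in CA1-like neurons (11 of 11 up, adjusted p = 1.75e-08; adjusted p = 0.888 with an estimated correlation) and in excitatory neurons as a class (11 of 13 up, adjusted p = 0.000734; adjusted p = 0.903 with an estimated correlation), and lower in astrocytes (11 of 12 down, adjusted p = 0.0274; adjusted p = 0.913 with an estimated correlation), with 4, 1 and 1 past adjusted over the list alone and 0 over all genes. Ribosomal protein genes were lower in astrocytes (57 of 73 down, adjusted p = 0.021; adjusted p = 0.913 with an estimated correlation) and heat shock genes higher in choroid plexus (13 of 16 up, adjusted p = 0.00234; adjusted p = 0.86 with an estimated correlation), with 0 members past either adjustment. Homeostatic astrocyte genes were higher in fibroblasts (8 of 9 up, adjusted p = 3.95e-07; adjusted p = 0.427 with an estimated correlation), where Gpc5 and Slc1a2, with 33.3% and 32.5% of their UMIs from 1 nucleus, passed over all genes and adjusted over the list alone, and lower in excitatory neurons (11 of 15 down, adjusted p = 0.0314; adjusted p = 0.903 with an estimated correlation), where 0 passed either.

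The study's question, whether VEGFC changes what injury does, is the difference between the VEGFC over GFP fold after TBI and after sham in the right hippocampus. It rests on 4 libraries without replicates, so the differences given here are values with intervals that cover counting error. A test that takes the left and right TBI libraries as replicates is given with the flagged results. Among 29236 gene and class pairs with at least 50 counts in each library, 138 differed by over 1 and 131 by under -1 on the log2 scale. The largest differences were Ptprd at 2.62 (95% interval 2.43 to 2.82), Hs3st4 at 2.58 and Arpp21 at 2.43 in mixed neurons, Nnat at 2.60 in fibroblasts and Lrp1b at 2.48 (1.86 to 3.1) in choroid plexus. The smallest were Foxp2 at -2.48 (-2.88 to -2.08) in excitatory neurons and Gpc5 at -2.36, Foxp2 at -2.26 and Sox2ot at -2.09 in mixed neurons, together with Ttr at -2.03 (-2.16 to -1.90) in excitatory neurons. Ttr, the transthyretin gene of choroid plexus epithelium, stood in excitatory neurons at 187 and 330 CPM in sham GFP and sham VEGFC and at 301 and 130 CPM in TBI GFP and TBI VEGFC. Mixed neurons were 46 nuclei in TBI GFP right and 160 in TBI VEGFC right, so values within that class compare unequal samplings of it. Excitatory cluster 5 was 2.23% and 3.13% of nuclei in sham GFP and sham VEGFC, and 4.73% and 1.425% in TBI GFP right and TBI VEGFC right, so values in excitatory neurons also compare unequal mixes of clusters.

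**Figure D4:**
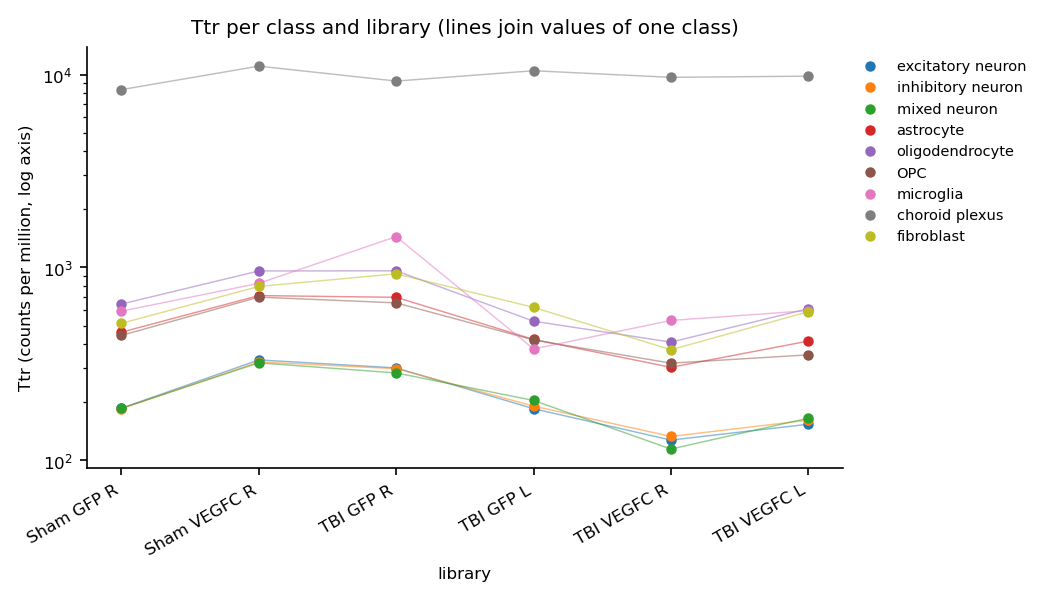
Ttr in CPM (vertical log axis) in the summed nuclei of each class (colour) in the 6 libraries (horizontal axis). Choroid plexus stood at 8349 to 11050 and the other 8 classes at 114.6 to 1445, with their highest values in sham VEGFC right or TBI GFP right.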

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

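In this part the interaction test was planned as an alternative, the bounds for free RNA of other classes were set before that result was seen, and all other tests were chosen after the results were seen.

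Genes were counted whose vector effect after TBI and after sham differed at an adjusted p under 0.05 in edgeR when the right and left TBI libraries were taken as replicates of injury. Each sham arm is 1 library, so the spread in this test comes only from left against right TBI libraries, and the counts do not show a difference beyond the spread between sham samples. Mixed neurons had 81 genes with a higher VEGFC effect after TBI than after sham and 45 with a lower one. The counts were 6 and 19 in excitatory neurons, 2 and 8 in choroid plexus, 5 and 5 in astrocytes, 6 and 9 in oligodendrocytes, 4 and 3 in OPC, and 3 and 1 in fibroblasts. Left and right libraries may also come from the same animals, a point on which the correlation of 0.271 given next decides nothing. The share of microglia had a log2 ratio of VEGFC over GFP of -1.29 in sham and the other sign in both TBI contexts, a difference that was not tested. Inhibitory neurons, at 0.30 in sham, and OPC, at -0.34, also had the other sign in both TBI contexts. This did not hold without the clusters taken as neighbouring tissue, whose place in or outside the hippocampus was not tested.

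Across genes, the vector folds of the right and left TBI libraries, which share no library, correlated at 0.271 in excitatory and 0.612 in mixed neurons. They correlated at 0.054 in inhibitory neurons and 0.132 in the interneuron subset. For sham right with TBI right the excitatory value was -0.04. In mixed neurons sham right correlated at -0.455 with TBI right and at -0.435 with TBI left. Genes are not independent replicates. In excitatory neurons, a different mix of clusters is argued against by a correlation of 0.312 within the single CA1-like cluster and 0.336 within the single CA3-like one. Free RNA of classes that are not neurons is argued against by 0.252 over 727 genes at least 5 times higher in excitatory neurons than in those classes. Free RNA of inhibitory and mixed neurons is not addressed, since these classes were left out of that comparison. That the right and left libraries of each vector came from the same mice cannot be told apart from a vector effect after injury, since the labels do not give the animals, and both stay open as hypotheses.

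Microglia were 3.75% of nuclei in TBI VEGFC left. Fewer neurons as the whole cause is argued against by the highest share among nuclei that are not neurons, 3.96 times the lowest. Only 7.2% of microglia in this library had a doublet score above 0.08, against at least 23.8% in each of the other 5, which is consistent with the limit on deposited scores having removed more microglia elsewhere. The larger share may therefore be technical in part; a larger microglial population in that hippocampus stays open and was not tested.

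Ttr, Apod, Ptgds, Cst3 and Apoe, abundant in choroid plexus, fibroblasts or glia, had a lower VEGFC effect after TBI than after sham in several classes. For Ttr the median difference of folds over 8 classes was -1.91, against -0.32 in choroid plexus, which makes it. This is consistent with free RNA that differed between libraries, and a change within the other classes was not tested apart from it.

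The vector count over 9 classes was set against the 10 splits of the 6 libraries into 3 and 3, of which 6 gave at least the 23 genes of the real split and the highest other gave 457. This does not measure chance for the vector, because with the context term 6 of the splits each reduce to a single pair of libraries and come as duplicates with 39, 457 and 18 genes. The splits with 457 genes compare TBI GFP left with TBI VEGFC left. Only 4 splits part the libraries of every context as the vector does, and they gave 23 (the real one), 8, 13 and 110 genes. The split with 110 genes sets sham GFP and both TBI VEGFC libraries against the other 3. With so few splits no share under 0.05 can be reached.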

How the results depend on the processing

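Scores of at most 0.05, removal of neuronal-RNA nuclei and removal of neighbouring tissue were chosen after the results were seen; the other settings were planned. The vectors were paired within the 3 contexts by the context term, and the labels' replicate numbers, which no groups share, give no further pairing. RLE factors kept every gene named by the rule past its threshold with its direction, and the 1000 UMI minimum removed no nucleus and tests nothing. Unless a construction is named, the cause was not tested.

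For VEGFC, the 13 higher and 10 lower genes became 99 and 137 without a filter, mostly in excitatory and inhibitory neurons, 0 and 0 with DESeq2 (420 at an unadjusted p under 0.05; edgeR 4425, limma-voom 19 and 14 genes), 4 and 5 with low doublet scores, where 6 classes remained, and 5 and 3 with no context term. Leaving out 1 library gave 11 to 220 higher and 12 to 170 lower. For TBI, 32 and 32 became 79 and 91 without a filter, 4 and 3 with DESeq2, 10 and 7 with equal numbers of nuclei, 21 and 12 with low doublet scores, and 25 to 92 and 24 to 99 without 1 library; without glial nuclei high in neuronal RNA 16 were lower. On the left, 25 higher and 1 lower became 88 and 16 without a filter, 3 and 0 with DESeq2 (171 at an unadjusted p under 0.05), 16 and 2 with limma-voom, 1 and 3 with low doublet scores, and 18 to 233 and 2 to 57 without 1 library; 9 were higher without nuclei high in neuronal RNA, and 2 were lower with library totals and with equal numbers of nuclei. A left-out library leaves 1 context with a lone library, which then adds nothing to the vector contrast and is assumed to vary like the others. With an estimated correlation 0 gene lists passed in either direction of the 3 comparisons; with the preset correlation 19, 20 and 13 of 217 did.

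Mean log2 ratios of shares changed sign in some settings. With low doublet scores they were -0.155 for excitatory neurons and 0.054 for OPC, and without neighbouring tissue -0.027 for excitatory neurons, 0.025 for inhibitory neurons and -0.039 for astrocytes. Without 1 library they ranged from -0.020 to 0.083 in excitatory, -0.357 to 0.130 in inhibitory and -0.922 to 0.613 in mixed neurons, -0.030 to 0.067 in astrocytes, -0.324 to 0.443 in oligodendrocytes, -0.119 to 0.159 in OPC, -0.361 to 1.46 in microglia and -0.572 to 0.002 in fibroblasts. Among named genes, the TBI fold of Hpse2 in astrocytes ranged from -0.204 without replicate 5 to 4.81, that of Epha6 was 0.164 with low doublet scores, and the left-right fold of Slco1a4 in oligodendrocytes ranged from -6.28 to 0.613 without replicate 3. Of the genes named past the threshold, 21 for VEGFC, 48 for TBI and 16 for left against right, DESeq2 kept 0, 4 and 2 past it.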

Other observations

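The list tests in this part use the planned gene lists, on classes of the authors and on neuron subsets that were formed after the results were seen.

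In dentate granule-like neurons 7 of 8 interferon genes were higher with VEGFC (adjusted p = 0.0173; adjusted p = 0.982 with an estimated correlation), 2 past the threshold adjusted over the list alone and 0 over all genes in edgeR; Ifit1, at 2.57 (SE 0.65), had 15.4% of its UMIs from 1 nucleus. In CA3-like neurons 14 of 18 unfolded protein response genes were higher with VEGFC (adjusted p = 0.0328; adjusted p = 0.939 with an estimated correlation), with 0 past either adjustment. In the interneuron subset 13 of 14 oxidative stress genes (adjusted p = 0.00902), 11 of 17 glycolysis genes (adjusted p = 0.0251), 15 of 21 cholesterol synthesis genes and 49 of 73 ribosomal protein genes (adjusted p = 0.0252 each) were lower with VEGFC, all with an adjusted p = 0.868 with an estimated correlation. Adjusted over the list alone 2, 1, 0 and 0 passed, and 0 over all genes; the glycolytic enzyme gene Pgam1 was at -0.73 (SE 0.17).

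After TBI, mitochondrially encoded transcripts were higher in CA1-like neurons (11 of 11 up, adjusted p = 0.00935; adjusted p = 0.982 with an estimated correlation), with 1 past the threshold adjusted over the list alone and 0 over all genes. Immediate early genes were lower in CA3-like neurons (14 of 17 down, adjusted p = 0.0391; adjusted p = 0.86 with an estimated correlation), with 0 past either adjustment, and with library totals that list had an adjusted p of 0.0529. Matrix genes were higher in inhibitory neurons (15 of 17 up, adjusted p = 0.0285; adjusted p = 0.959 with an estimated correlation), 1 past adjusted over the list alone and 0 over all genes. In fibroblasts 6 of 6 disease-associated oligodendrocyte genes were lower (adjusted p = 0.0161) and 25 of 34 ribosomal protein genes higher (adjusted p = 0.0373), both with an adjusted p = 0.619 with an estimated correlation; 1 and 0 passed adjusted over the list alone and over all genes. On the left, homeostatic astrocyte genes were lower in dentate granule-like neurons (11 of 13 down, adjusted p = 0.00121; adjusted p = 0.998 with an estimated correlation), with 0 past either adjustment. Matrix genes were lower in the interneuron subset (8 of 11 down, adjusted p = 0.00539, and adjusted p = 0.905 with an estimated correlation), with 2 past adjusted over the list alone and 1, Hapln1, over all genes. In that subset matrix genes were higher for TBI against sham. Both comparisons use the TBI right libraries, so these opposite signs are not independent.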
